A study of Homo sapiens with 4 samples.

How the data were processed

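Gene expression was measured in HEK293T cells on 4 two-colour spotted cDNA arrays, each hybridised with RNA of cells starved of serum for 3 days and RNA of cells in 10% fetal bovine serum (day 0). The labels give the dye of each RNA, with starved RNA in Alexa555 on 2 arrays and in Alexa647 on 2 arrays. Replicate numbers follow the order of the records and are names only.

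The deposited scanner files hold, per the file headers, spot amplitudes (intensity, linear scale) from BlueFuse for Microarrays 3.6, with Alexa555 as channel 1 and Alexa647 as channel 2. The log2 ratio of channel 1 over channel 2 in the same deposited files equals the log2 ratio of these amplitudes to rounding, so it carries no further normalisation. The deposited on-probability of a spot in each channel is a fraction between 0 and 1, per the file headers a column of the same software. The files mark spots excluded by hand or by the software. The deposited series table holds the authors' log2 ratios for part of the probes. Its centring and scale are not given in the sources used here. Set against the scanner values, its ratios ran as starved over serum on every array, with correlations across probes of 0.84 and 0.86 (starved-in-Alexa555 replicates 1 and 2) and 0.79 and 0.77 (starved-in-Alexa647 replicates 1 and 2) with the ratios computed here. Its column medians were -0.016, 0.0077, 0.0034 and -0.17 in this order.

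The scanner files hold no background column, no amplitude below 0, and no statement on background correction in the headers. The amplitudes were taken as already separated from the background by the software and used without further correction. This was decided from the file format before any test was run. Empty spots had a median Alexa647 amplitude of 231 to 343 on the 4 arrays, against 740 to 1393 for clone spots not excluded. In Alexa555 it was 41.5 to 88.6 against 665 to 1056. The choice is therefore uncertain, above all for Alexa647. The plan written before the data were examined names normexp with an offset of 50 for uncorrected intensities, so that correction is given beside the main count. Log2 ratios of Alexa647 over Alexa555 were normalised within each array by loess on mean log2 amplitude (span 0.3, 4 iterations) in R 4.3.3 with limma 3.58.1. Control, empty and blank spots (2822 per array) had weight 0 in that step and were left out after it, and so were excluded spots. The spots of a probe, usually 2, were averaged. A probe was tested with values on at least 3 arrays and an on-probability over 0.5 in 1 channel or more on at least 3 arrays. The on-probability removed 0 further probes, so that the spots marked as excluded alone set the list of 6216 tested probes. The other 7373 clone probes had values on fewer than 3 arrays.

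The ratios were fitted with lmFit and eBayes, with a term of 1 or -1 for the direction of starved over serum and an intercept for the dye effect, leaving 2 residual degrees of freedom per probe with 4 arrays and 1 with 3 arrays. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested probes. No called probe was off in the starved or the serum channel on every array, so fold changes are given as fitted and not as bounds, although some ratios are set against a channel not called on. On simulated ratios with the real dye effects and spreads (comparison of starved against serum, 6216 probes, 200 of them changed), the fit recovered 22% of changes of 0.5, 94% of changes of 1, and 100% of changes of 1.5 and of 2 on the log2 scale, with 15 false calls among 173. That simulation drew errors of the same spread on every array and says nothing on errors shared between arrays.

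None of the 13244 clone names matched a symbol or synonym in the RefSeq gene table used here, and gene names for the clones are not given in the sources used here. Lists of genes fixed before the data were examined could therefore not be applied, and no gene list test was run. The rule for named genes, written before the data were examined, takes per direction the 12 largest absolute log2 fold changes among called genes with the same direction on all 4 arrays. Since no gene name was available, the 2 first probes of that ranking were named per direction.

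Alternatives were normexp with offsets of 50 and 10, median centring, print-tip loess, Aquantile normalisation between arrays, no filter on dim probes, both channels on across all 4 arrays, no dye term, the authors' series table, excluded spots kept, array weights, the mean over probes of a clone, each array left out, the image session as a block, an absolute log2 fold change of at least 1, and a one-sample test without variance shrinkage. Further alternatives were chosen after seeing the data: arrays scaled to one median absolute deviation, the same after print-tip loess, an on-probability over 0.9, the brightest group of probes alone under loess and under print-tip loess, and probes with values on all 4 arrays.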

Results

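The series compared RNA of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, after 3 days without serum with RNA of cells kept in medium with 10% fetal bovine serum (day 0). Both RNAs were hybridised together on 4 spotted cDNA arrays. Starved RNA was labelled with Alexa555 and serum RNA with Alexa647 on 2 arrays, here called starved-in-Alexa555 replicates 1 and 2, and the dyes were exchanged on the other 2 arrays, called starved-in-Alexa647 replicates 1 and 2. Each array held 30000 spots in 48 print blocks, of which 27178 spots carried 13589 clone probes. The files give a probe identifier and a clone name but do not pair either with a gene, so probes are reported by identifier. Of the clone spots, 52.8% and 53.8% were marked as excluded on the starved-in-Alexa555 arrays, and 67.6% and 34.7% on the starved-in-Alexa647 arrays, replicates 1 and 2 in this order. The signal over background in Alexa555 was 4.75, 4.01, 3.96 and 5.49, and in Alexa647 it was 4.06, 3.73, 2.97 and 4.29, in the same order of arrays. A ratio on at least 3 arrays was available for 6216 probes, and on all 4 arrays for 4489 of them. The labels do not say whether the 4 arrays came from separate cultures. With the dye effect in the fit, p-values measure only the spread between arrays of the same dye orientation, which may be technical. Differences of the starved over serum ratio between the 2 orientations go into the dye effect and do not widen the SE. A dye bias that differs in size between the orientations shifts the fold change instead. The median absolute deviation of the log2 ratios was 0.59 and 0.68 on the starved-in-Alexa555 arrays. On the starved-in-Alexa647 arrays it was 0.85 and 1.33. The fit therefore does not free the fold changes of such a bias. The number of arrays limits the precision of every fold change.

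The first comparison asked which transcripts differed between serum-starved and serum-supplemented cells. Of the 6216 probes, 51 rose and 163 fell in starved cells (limma, Benjamini-Hochberg adjusted p under 0.05). The called risers had a median log2 fold change of 0.94 (1.92-fold) and the called fallers of -1.07 (2.10-fold), and absolute values ran from 0.77 to 2.19. Of the 214 called probes, 163 had values on all 4 arrays. The ratio had the same sign on all 4 arrays for 119 of these, 39 of which rose and 80 of which fell. Among these, the probes with the largest changes were hcs136d04 and hcs092c04, which rose, and hcs139d01 and hcs009c12, which fell. The probe hcs092c04 (clone fg023c05) rose by a log2 fold change of 1.68 (SE 0.17, n = 4 arrays, limma adjusted p = 0.0227), with ratios between 1.55 and 1.80 on the single arrays. The probe hcs136d04 (clone hd017a07) rose by 1.69 (SE 0.17, n = 4 arrays, limma adjusted p = 0.0227). Its ratios were 2.60 and 2.52 on the starved-in-Alexa555 arrays but 0.97 and 0.67 on the starved-in-Alexa647 arrays. The probe hcs139d01 (clone cs105d05) had a log2 fold change of -1.47 (SE 0.20, n = 4 arrays, limma adjusted p = 0.0437), made up of -0.43 and -0.01 on the starved-in-Alexa555 arrays and -2.36 and -3.08 on the starved-in-Alexa647 arrays. The probe hcs009c12 (clone bx013h10) had a log2 fold change of -1.46 (SE 0.25, n = 4 arrays, limma adjusted p = 0.0437), and its ratios were -0.48 and -0.37 against -1.72 and -3.25. The fold change of hcs009c12 was smaller after print-tip loess (-0.84) and in the authors' series table (-0.81). The starved channel was on for hcs139d01 on 3 of the 4 arrays and for hcs009c12 on 2 of them, and the serum channel of both on all 4, so that part of each ratio is set against a channel not called on. The median log2 fold change over all tested probes was -0.11. Print block accounted for 18.3% of the variance of the fold changes across probes under loess (adjusted R-squared). After print-tip loess the share was 1.42%, a fall set by construction, since that step centres the ratios within each block.

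**Figure D1:**
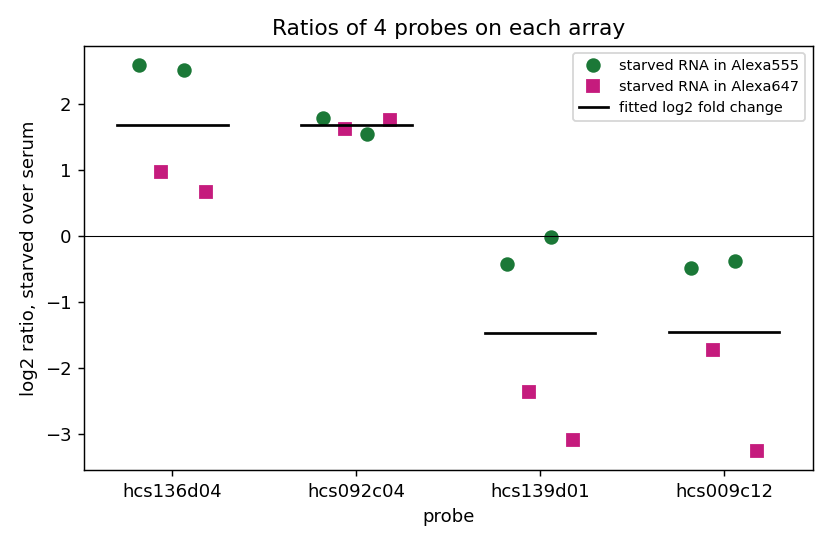
Log2 ratio of starved over serum RNA on each array (vertical axis) for the probes hcs136d04, hcs092c04, hcs139d01 and hcs009c12 (horizontal axis), with circles for arrays with starved RNA in Alexa555, squares for arrays with starved RNA in Alexa647 and a line at the fitted log2 fold change. All 4 ratios of hcs092c04 lie between 1.55 and 1.80, while those of hcs139d01 run from -3.08 to -0.01 and separate by dye.

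The count of called probes lay close to the threshold, with a smallest adjusted p of 0.0227 and with 1710 probes at an unadjusted p under 0.05. With the normexp background correction at an offset of 50, limma called 0 probes, with 1670 at an unadjusted p under 0.05, and the adjusted p of each of the named probes was 0.0689. Without single arrays the count was 2 (starved-in-Alexa555 replicate 1), 5 (starved-in-Alexa555 replicate 2), 2515 (starved-in-Alexa647 replicate 1) and 1059 (starved-in-Alexa647 replicate 2). In each of these fits the residual spread came only from the remaining pair of arrays of the same orientation, and the tested probes differed. These counts therefore do not measure the size of the starvation effect. The split between risers and fallers moved too: 20 rose and 232 fell after median centring, 102 rose and 238 fell after print-tip loess, 98 rose and 188 fell when the arrays were scaled to one spread, and 540 rose and 519 fell without starved-in-Alexa647 replicate 2. The probes hcs092c04 and hcs136d04 were the 2 probes still called without starved-in-Alexa555 replicate 1. There, hcs139d01 had a log2 fold change of -1.36 (limma adjusted p = 0.228) and hcs009c12 of -1.43 (limma adjusted p = 0.156).

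Called probes were counted by brightness, with the tested probes split by mean log2 amplitude into 4 groups of 1554. In the dimmest group 8 probes rose and 28 fell, in the second group 7 rose and 34 fell, in the third 8 rose and 41 fell, and in the brightest 28 rose and 60 fell. The share of called probes thus ran from 2.32% in the dimmest to 5.66% in the brightest group. With print-tip loess it ran from 2.90% to 10.9%, and in the brightest group 75 probes rose and 94 fell. Many probes of the dimmest group had no value on starved-in-Alexa647 replicate 1, so the groups differed in missing values as well. The probe hcs092c04 belonged to the brightest group, at the 87.7th percentile of amplitude, whereas hcs139d01 lay at the 73.7th, hcs136d04 at the 48.5th percentile and hcs009c12 close to the median.

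**Figure D2:**
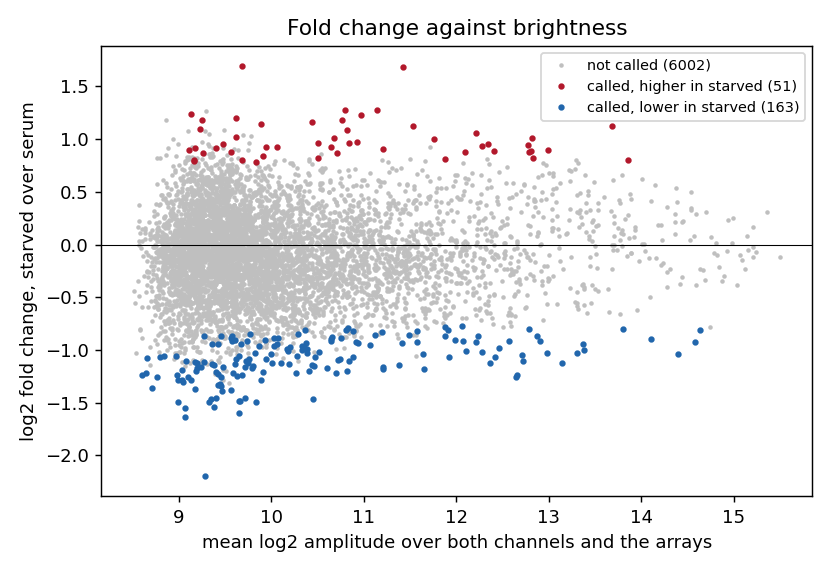
Log2 fold change of starved over serum (vertical axis) against the mean log2 amplitude over both channels and the arrays (horizontal axis), 1 point per tested probe. The 51 called probes above 0 and the 163 below 0 are coloured, and both kinds occur from dim to bright amplitudes.

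The second comparison measured the effect of the dye, the part of the Alexa647 over Alexa555 ratio that did not follow the RNA. It was called for 2601 of the 6216 probes (41.8%, limma adjusted p under 0.05), with 1125 probes brighter in Alexa647 and 1476 brighter in Alexa555. Brighter here means relative to probes of similar amplitude on the same array, since loess centred the ratios. The SD across probes was 0.86 for the dye effect and 0.43 for the starvation effect on the log2 scale. By brightness, the dye effect was called for 55.7% of the dimmest and 19.6% of the brightest group. Of the 214 probes called between starved and serum cells, 135 carried a called dye effect as well. Among them were hcs136d04 with a dye effect of -0.87, hcs139d01 with -1.25 and hcs009c12 with -1.03 (limma adjusted p = 0.00521, 0.00185 and 0.0123). That of hcs092c04 was 0.01 (adjusted p = 0.964). Fallers lay mostly among probes brighter in Alexa555: when the tested probes were split into 5 groups by dye effect, 97 of the fallers and 1 of the risers lay in the lowest group, and 0 of the fallers and 17 of the risers in the highest. Across all tested probes the starvation and dye effects correlated with r = 0.51. With the arrays scaled to one spread r was -0.19, and -0.0087 with print-tip loess as well. In this fit the correlation mostly reflects which pair of arrays has the wider ratios, here the starved-in-Alexa647 arrays. Scaling to one spread therefore largely removes it by construction. The split of fallers by dye effect shares this limit. Among the 1752 probes with an absolute dye effect under 0.25, 17 rose and 22 fell.

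The agreement of the arrays was measured across probes, which are not independent replicates, on ratios turned to starved over serum. Pearson's r was 0.85 between the starved-in-Alexa555 arrays and 0.80 between the starved-in-Alexa647 arrays. Between arrays of opposite dye orientation it lay between -0.62 and -0.53, so that the direction of every fold change above rests on the dye labels, which the labels and the headers of the scanner files give alike. In the brightest group of probes r was 0.84 and 0.75 within, in the same order, and between -0.14 and -0.02 across orientations. In the dimmest group it was 0.86 and 0.87 within and between -0.80 and -0.70 across them. There, pairs with starved-in-Alexa647 replicate 1 rested on 590 to 653 probes and the other pairs on 1463 to 1526. The groups thus differ in missing values of that array as well as in brightness.

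**Figure D3:**
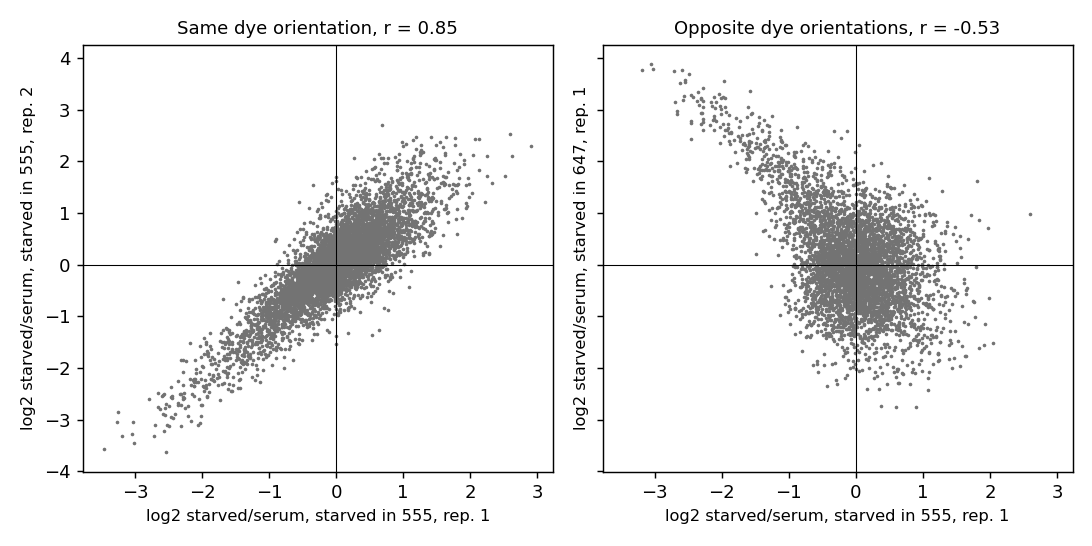
Log2 ratios of starved over serum RNA of starved-in-Alexa555 replicate 1 (horizontal axes) against those of starved-in-Alexa555 replicate 2 (left) and starved-in-Alexa647 replicate 1 (right), 1 point per tested probe. The ratios rise together on the left (r = 0.85) and run against each other on the right (r = -0.53).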

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

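The tests of explanations below were chosen after the results were seen. A difference between the dye orientations flagged 2601 of the 6216 probes, since their starved over serum ratio differed between arrays with starved RNA in Alexa555 and in Alexa647 (the dye term of the limma fit, adjusted p under 0.05). Of the named probes, hcs136d04 (dye effect -0.87), hcs139d01 (-1.25) and hcs009c12 (-1.03) were among them.

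The turned ratios of arrays with opposite dye orientation correlated below 0 across probes, which arrays of the same RNAs with exchanged dyes would not show if the RNA set most of the ratio. A trend with intensity or print block left by the normalisation is argued against, because after print-tip loess the median over 20 brightness bins of the mean correlation was still -0.61, and it was under -0.1 in 17 bins. In the 3 brightest bins it was 0.0065, 0.18 and 0.49. Arrays that all had 1 orientation, with no exchange of dyes, are argued against as well: the brightest pairs of opposite orientation would then lie as far below 0 as pairs of the same orientation lie above, but the 2 mean correlations summed to 0.71. Alexa647 signal that does not come from the labelled RNA and weighs most in dim spots stays open. The mean correlation of opposite orientations was higher by 0.67 in the brightest than in the dimmest group, and empty spots had 3.24 to 8.27 times the amplitude in Alexa647 as in Alexa555 on the 4 arrays, but Alexa555 signal of that kind would give the same difference, and the control spots exceeded the empty spots on all 4 arrays in Alexa555 but not in Alexa647. No biological explanation was tested for this pattern, because each array held both conditions.

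More called probes fell than rose, 163 against 51 (76.2% falls, 95% exact interval over probes 69.9% to 81.7%). The intervals in this paragraph take probes as independent, although all share the same 4 arrays, so they are too narrow for a spread between arrays. Whether a dye effect wider on the arrays with starved RNA in Alexa647 was the whole cause stays open, since the values go both ways: falls still made up 65.7% of the called probes (interval 59.9% to 71.2%) after the arrays were scaled to one spread, but 56.4% (39.6% to 72.2%) among those with an absolute dye effect under 0.25. The array with the widest ratios, starved-in-Alexa647 replicate 2, is a candidate source of the excess. Among the 4489 probes with values on all 4 arrays, falls made up 69.6% of the 214 probes with the smallest p, 51.4% without that array (interval 44.5% to 58.3%), and 77.1% to 92.5% without any other single array. The 163 called probes in that set kept their directions without it, 116 of them below 0. The count below 0 was 116 without each other single array too, so it does not bear on this array. The median log2 fold change was -0.11 over the 6216 tested probes and 0.01 over the 4498 tested without this array. A median below 0 favours falls, and its part in the excess was not tested. That serum withdrawal lowered more transcripts than it raised stays open too. In the brightest group, where the dye effect was smallest but still present, falls made up 68.2% of the called probes under loess and 55.6% after print-tip loess. With both channels on across all 4 arrays, 24 probes rose and 21 fell.

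Of the 3 splits of the 4 arrays into 2 and 2, only the real one called any probes, 214 against a highest of 0 in the others. With 3 splits, a share under 0.05 cannot be reached. In the other splits the difference between the dye orientations falls into the residual spread and widens it. Few calls were therefore likely there from the start, and the comparison cannot decide on chance.

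A signal outside the main measurement appeared in the control spots. All 8 control sequences, 192 spots each, had a median Alexa555 amplitude above that of the empty spots on all 4 arrays, by 3.27 times in the median (1.19 to 8.02). In Alexa647, 0 of the 8 lay above the empty spots on all 4 arrays, and the median ratio was 0.715.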

How the results depend on the processing

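Scaling to one spread, an on-probability over 0.9, the brightest group alone and values on all 4 arrays were chosen after seeing the data. Aquantile normalisation, no filter on dim probes (which removed 0 probes) and the mean over probes of a clone each gave 214 called probes, all of them shared with those reported. The cause of the changes below was not tested.

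In limma fits, 0 probes were called (0 rose, 0 fell) with normexp at offset 50 (1670 at an unadjusted p under 0.05), normexp at offset 10 (1607), no dye term (269) and excluded spots kept (1976, over 11098 probes, dye effect called for 4943). The one-sample test without variance shrinkage called 0 as well (0 rose, 0 fell, 474 at an unadjusted p under 0.05). Array weights left 2 called (2 rose, 0 fell), and so did the 4489 probes with values on all 4 arrays (2 rose, 0 fell, dye 1474). With both channels on across all 4 arrays (3427 probes), 45 were called (24 rose, 21 fell, dye 644, mean correlation of opposite orientations -0.313 against -0.575). An absolute log2 fold change of at least 1 left 122 (19 rose, 103 fell). Median centring called 252 (20 rose, 232 fell, 140 shared with those reported, mean correlation -0.652). Print-tip loess called 340 (102 rose, 238 fell, 135 shared, mean correlation -0.521), and the series table of the authors called 301 (94 rose, 207 fell, 125 shared, mean correlation -0.524). Arrays scaled to one spread gave 286 (98 rose, 188 fell, 138 shared), and with print-tip loess as well 414 (154 rose, 260 fell, 140 shared, mean correlation -0.521). The brightest group alone gave 428 of 1554 (162 rose, 266 fell, dye 319, mean correlation -0.084), and with print-tip loess 547 (225 rose, 322 fell, dye 332, mean correlation -0.053).

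The image session as a block called 1059 (540 rose, 519 fell) over 4498 probes. That session term holds 1 array, starved-in-Alexa647 replicate 2, and gave the same values as leaving it out. Without 1 array at a time (1 residual degree of freedom), the count ran from 2 to 2515, risers from 2 to 600, fallers from 0 to 1915, the dye count from 643 to 3829 and the mean correlation from -0.593 to -0.517. The low counts came without an array with starved RNA in Alexa555, the high ones without an array with starved RNA in Alexa647. Each such fit takes its residual spread only from the remaining pair of arrays of the same orientation. A higher count is therefore not a larger starvation effect. Over all tested probes the median log2 fold change was -0.11, and it was 0.01 without starved-in-Alexa647 replicate 2.

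The 4 named probes kept their direction under every alternative that measured them. They were chosen for the same sign on all 4 arrays. Leaving out an array, array weights, a fit without the dye term and filters on probes could therefore not turn it. Settings that repeated another fit counted once, hcs092c04 was called in 15 of 20 (log2 fold change 1.42 to 1.76, adjusted p 0.00178 to 0.960), hcs136d04 in 12 of 17 (1.58 to 2.00), hcs139d01 in 9 of 17 (-1.75 to -1.14) and hcs009c12 in 8 of 17 (-1.84 to -0.81). Each ratio is already the paired difference of starved and serum RNA on 1 array, and the replicate numbers pair no arrays. The day of analysis could not be fitted as a block, since its 3 days left no residual degree of freedom. It need not be the slide or scan date. Gene lists, camera with an estimated correlation and fry were not run, because the probes carry no gene names. A signal over background of 2.97 to 5.49 limits the ratios of dim probes.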

Other observations

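The tests in this part were chosen after the results were seen. With normexp at either offset and with excluded spots kept 0 probes were called, and with array weights 2, so that no probe was called under every setting. The probes called under loess and under each of 5 other scalings numbered 61, of which 8 rose and 53 fell. These scalings were median centring, print-tip loess, arrays scaled to one spread, both together, and the authors' series table. Among the 61 probes, the risers had a median log2 fold change of 1.21 and the fallers of -1.05. Values on all 4 arrays with the same sign were found for 53 of the 61, and 40 lay in the brightest group of probes.

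The clone names of the tested probes fall into 15 series by their first letters, whose meaning is not given in the sources used here. Risers and fallers of each series were set against all other series by Fisher's exact test under both normalisations, 60 tests in all, which take probes as independent. After print-tip loess, 22 of the 258 probes of series by rose (8.53% against 1.34% elsewhere, Fisher's exact p = 9.95e-11, adjusted p = 5.97e-09). Under loess 6 of them rose (2.33% against 0.755%, Fisher's exact p = 0.0181, adjusted p = 0.124). In series cs, the largest with 1932 probes, 14 rose after print-tip loess (0.725% against 2.05%, adjusted p = 0.00169) and 13 under loess (0.673% against 0.887%, adjusted p = 0.817). In series bx 43 of 736 probes fell after print-tip loess (5.84% against 3.56%, adjusted p = 0.0376) and 26 under loess (3.53% against 2.50%, adjusted p = 0.374). In series hq 4 of 82 probes rose under loess (4.88% against 0.766%, adjusted p = 0.0376) and 2 after print-tip loess (adjusted p = 0.757). Of the 60 tests, 1 passed under loess and 6 after print-tip loess, and 0 combinations of series and direction passed under both. The median dye effect of a series ran from -0.62 in series by to 0.58 in series oe.

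The dye effect differed between probes, and source plate (the first part of the probe identifier, 142 plates) accounted for 25.9% of its variance under loess and 30.9% after print-tip loess (adjusted R-squared). For print block the shares were 21.4% and 0.149%, the second low by construction. Of the starvation effect, plate accounted for 8.14% and 10.3%. A property of the clone sequence is argued against as the main source by 19 clones that were tested at 2 places, always from different plates: their dye effects correlated with r = -0.34 under loess (95% interval -0.69 to 0.14, permutation p = 0.156) and 0.0035 after print-tip loess (-0.45 to 0.46), which leaves room for a moderate share of the clone sequence. Their starvation effects correlated with r = 0.63 (rho = 0.62, permutation p = 0.00412, adjusted over 4 relations 0.0165) under loess, and with r = 0.35 (permutation p = 0.136) after print-tip loess. Without the 2 clones farthest from the median, r was 0.58 and 0.25. What sets the dye effect of a plate was not tested, and no biological explanation was tested.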
